A study of Mus musculus with 4 samples.

How the data were processed

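RNA from macrophages of mouse ear dermis was measured on 4 Affymetrix whole-transcript expression arrays, 2 for each of 2 sorted subsets, CX3CR1low and CX3CR1bright. Per the labels, the animals were untreated adult C57Bl/6 mice that carried GFP in place of 1 of their Cx3cr1 alleles. The cells were isolated by fluorescence-activated sorting from digested skin of 3 to 6 pooled mice per sample, and the 2 samples of a subset came from 2 independent litters. Total RNA was purified with a micro-scale column kit and labelled with the Affymetrix WT Pico reagents, per the labels' protocols, a kit that amplifies small amounts of RNA before hybridisation.

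The deposited values are log2 expression levels made with RMA in Affymetrix Expression Console 1.4, per the submitters' processing notes. RMA subtracts an estimated background, equalises the distribution of the arrays and summarises the probes of each transcript into 1 value. Genome build and annotation release are not given in the sources used here, so no coordinates are printed. The scanner images and probe intensities were not used here, so the background correction and the summarisation could not be varied. Detection calls were not used here, and a level near the array median, 3.65 to 3.68 on the log2 scale, can be background.

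The table held 34390 transcript clusters. Of these, 23521 carried 1 gene symbol in the platform annotation, 1814 carried several and 9055 carried none. Gene names were taken from single-symbol clusters alone. By Entrez identifier 23328 of them matched the RefSeq gene table of assembly GRCm38.p6, which was used for names alone and updated 0 symbols, and the other 193 kept the annotation's symbol. Where a gene had several clusters, the cluster with the highest mean over the 4 arrays was used, which left 22180 genes. A gene was tested if at least 2 of the 4 arrays lay above that array's own median, which left 13133 genes. All array columns of the table were used.

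Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default variance prior, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are CX3CR1bright minus CX3CR1low on the log2 scale, with the moderated SE. The fit had 2 residual degrees of freedom and took 3.28 more from the prior. With 2 arrays in each group the number of arrays limits the precision, and p-values measure the spread between pools of mice, not between single animals. The same-numbered replicates of the subsets are not said to share a litter, and the number was not used as a block.

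A set of 25 gene lists covered macrophage states and functions and the other cell types that a sort from skin could hold. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 25 lists, and again with an estimated correlation and with fry. Of 496 listed genes, 420 were tested, 44 were too dim for the filter and 32 were not analysed here. For 1 gene the listed name was an older synonym. The named genes are the 12 with the largest difference in each direction among genes past the threshold with no overlap between the groups, leaving out predicted genes, clone-derived genes and small RNAs. Where fewer than 12 passed, the remaining places went to the genes with the smallest p among those with at least a 2-fold difference and no overlap. Cx3cr1 and the 4 members of each list with the smallest p were added. The grouping, the test, the lists, the rule for named genes and all but 1 of the alternative settings were set before the data were examined. Genes outside the lists and that rule are marked in the text as chosen after their values were seen. Some further list members, such as Lyve1, Ccl2, Ccl12 and Tnf, fall outside the rule and are given values without that mark.

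The procedure was tested on simulated data, in 20 simulations with 1000 changed genes at each of 4 sizes in all. The data took the means of the 13133 genes and spreads drawn from the fitted variance prior, regardless of level. It recovered 1.9% of genes changed by 1 on the log2 scale, 72.9% at 2, 92.6% at 3 and 96.7% at 4, and it called 150 of 258660 unchanged genes. Lists of 20 genes shifted by 1 were called in 20 of 20 cases, and 0 of 500 unshifted lists were. The simulated genes varied independently and the unshifted lists held random genes. The 0 of 500 therefore does not cover lists of genes that vary together. Nor need the recovery rates hold for the arrays, where spread may depend on level. There an intensity trend moved the count past the threshold from 18 to 308.

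Alternatives were other filters on dim clusters, all clusters with or without a name, the mean of a gene's clusters, quantile normalization, median centring and cyclic loess of the deposited values, an intensity trend and a robust variance prior, the replicate number as a block, each array left out in turn, other thresholds, a test against a 1.5-fold difference, and other set tests. The combination of intensity trend and robust prior was added after the data had been seen. With an array left out, the lone sample of its group is assumed to vary like the other group.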

Results

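Transcript levels were measured in 2 macrophage subsets of the adult mouse dermis that were separated by their level of CX3CR1, the receptor for the chemokine fractalkine. The mice carried a GFP reporter in 1 Cx3cr1 allele, so that fluorescence follows the activity of the gene. The series holds 4 arrays, 2 of CX3CR1low and 2 of CX3CR1bright macrophages, each from a pool of 3 to 6 mice. The values are RMA log2 levels, and the 4 arrays had medians of 3.65 to 3.68 and 75th percentiles of 5.44 to 5.52. Across 13133 tested genes, the CX3CR1low arrays correlated at r = 0.978 and the CX3CR1bright arrays at r = 0.960, against 0.938 to 0.960 between subsets, where genes are not independent replicates. CX3CR1bright replicate 1 correlated as closely with CX3CR1low replicate 1 (0.95986) as with CX3CR1bright replicate 2 (0.95962). The first principal component held 58.4% of the variance and placed the CX3CR1low arrays at -27.4 and -32.5 and the CX3CR1bright arrays at 18.7 and 41.2. The second held 27.2% and placed the CX3CR1low arrays at 5.34 and -14.8 and the CX3CR1bright arrays at 32.2 and -22.7.

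The comparison asks how the transcriptomes of the 2 dermal subsets differ. Cx3cr1 itself (transcript cluster 17532268), which defined the gate and so checks the labels, stood at 8.43 ± 0.011 (SD, n = 2) in CX3CR1bright and at 3.62 ± 0.023 (SD, n = 2) in CX3CR1low cells. The difference was 4.82 ± 0.18 (SE) on the log2 scale, 28.2-fold, with an adjusted p of 0.00966 (limma). The CX3CR1low level lay below the array median, so the fold is limited by background. With 1 array left out the difference was 4.80 to 4.83, but the adjusted p was 0.241 without CX3CR1low replicate 1, 0.248 without CX3CR1low replicate 2 and 0.0516 without CX3CR1bright replicate 2. Values below are log2 differences, CX3CR1bright minus CX3CR1low, with the SE and n = 2 per subset.

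Besides Cx3cr1, 7 genes were higher and 10 lower in CX3CR1bright macrophages, all by more than 2-fold. The largest difference among the higher genes was that of F11r (cluster 17219362), which encodes the junctional adhesion molecule JAM-A, at 3.94 ± 0.23 or 15.3-fold, with levels of 9.26 ± 0.22 and 5.32 ± 0.27 (SD, n = 2). F11r is also an epithelial gene; it stood at 9.10 and 9.41 on CX3CR1bright replicates 1 and 2, where keratinocyte markers lay 0.52 and 2.49 above the CX3CR1low mean. Stat4, a transcription factor of interleukin-12 signalling, was higher by 2.82 ± 0.19, and Il21r, the receptor for interleukin-21, by 2.13 ± 0.18. The CX3CR1low levels of Stat4, 3.94 and 3.77, lay near the array medians, so its difference may be limited by background. The adaptor gene Stap1 was higher by 2.63 ± 0.20, Arap3, a GTPase-activating protein, by 2.48 ± 0.19, the cytoskeletal GTPase gene Septin3 by 2.46 ± 0.20, and Adam23, a member of the ADAM family, by 2.31 ± 0.18.

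Among the genes lower in CX3CR1bright cells were 3 C-type lectins of the Cd209 family, which bind glycans on pathogens and host cells. Cd209g (cluster 17498750) differed by -3.00 ± 0.22, with levels of 6.59 ± 0.12 against 9.59 ± 0.27 (SD, n = 2), Cd209b by -2.80 ± 0.23 and Cd209d by -2.32 ± 0.20. These paralogs are similar in sequence, so their probes may not separate them fully. Also lower were Enpep, the aminopeptidase that cleaves angiotensin II, at -2.78 ± 0.23, Atp6v0d2, a subunit of the proton pump that acidifies lysosomes, at -2.54 ± 0.21, and the coronin gene Coro2b at -2.44 ± 0.21. Chp2, a calcium-binding regulator of sodium-proton exchange, differed by -2.39 ± 0.19, Wfs1, an endoplasmic reticulum membrane protein, by -2.37 ± 0.20, Cnrip1, which binds the cannabinoid receptor, by -2.33 ± 0.18, and the orphan receptor gene Gprc5b by -2.28 ± 0.20. The 17 genes besides Cx3cr1 had adjusted p-values of 0.0476 to 0.0494. Of the genes that come next by p and did not pass, Axl, a receptor for Gas6 on apoptotic cells, differed by 2.66 ± 0.26, Plxdc2 by 3.12 ± 0.30, the immunoglobulin-like receptor gene Lilra5 by 2.71 ± 0.27 and Btbd35f2, of a multicopy family, by 2.11 ± 0.21 (adjusted p = 0.0541 for each). The CX3CR1low levels of Lilra5, 3.51 and 3.98, lay near the array medians and can be background. On the lower side Plekhg5 differed by -2.22 ± 0.20 (limma, adjusted p = 0.0530) and Pomk by -2.03 ± 0.19 (limma, adjusted p = 0.0541).

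**Figure D1:**
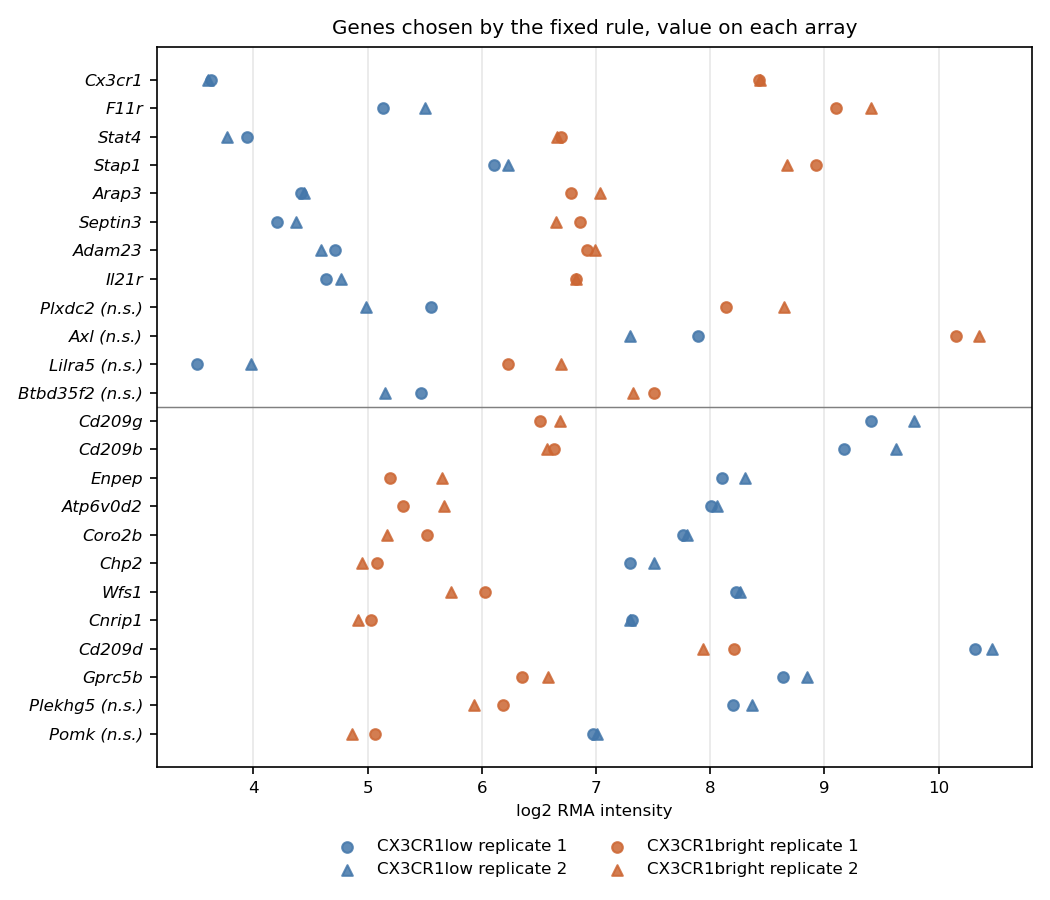
Log2 level of the 24 named genes on each of the 4 arrays (circles replicate 1, triangles replicate 2, blue CX3CR1low, orange CX3CR1bright), with genes higher in CX3CR1bright above the dividing line and lower ones below it, and n.s. marking genes not past the threshold. The CX3CR1bright arrays lie on 1 side of the CX3CR1low arrays for each gene drawn, by 4.82 for Cx3cr1 and -3.00 for Cd209g.

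In all, 18 genes passed the threshold. An unadjusted p under 0.05 (limma) was found for 2467 genes, 923 higher and 1544 lower, where 656.65 in total are expected by chance. At least 2-fold apart with no overlap between the subsets were 765 genes, 386 higher and 379 lower, or 462 and 260 after cyclic loess and 429 and 297 after quantile normalization. Groups without overlap made up 50.4% of tested genes, where chance gives 33.3%. The other splits of the arrays into pairs, by replicate number and crossed, gave 28.9% and 20.5%. They had 418 and 171 genes at an unadjusted p under 0.05 (limma). Nearly every gene lacks overlap in just 1 of the 3 splits, so some share must exceed 33.3% unless all are equal. The count of 18 was sensitive to the filter, the scaling, the variance model and single arrays. It was 1 without a filter and 464 with a stricter filter (174 higher and 290 lower). After quantile normalization it was 1, and the 3 Cd209 genes had an adjusted p of 0.0541 (limma). The count was 33 after cyclic loess (19 higher and 14 lower), 308 under an intensity trend (112 higher and 196 lower) and 1 under a robust prior. It was 0 without CX3CR1low replicate 1, CX3CR1low replicate 2 or CX3CR1bright replicate 2 (limma, with 1453, 1212 and 2180 genes at an unadjusted p under 0.05) and 154 without CX3CR1bright replicate 1.

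Of the 25 gene lists, 9 lay higher and 3 lower in CX3CR1bright macrophages than the other genes (camera with a preset correlation). All tested genes had a median difference of -0.070, or -0.12 with the stricter filter and 0.017 after cyclic loess. The list medians and member signs below are given without subtracting it. With an estimated correlation, which has 2 degrees of freedom here, 0 lists passed (3 at an unadjusted p under 0.05), and with fry, which asks whether a list moves on balance one way, the conventional dendritic cell and lysosome lists passed. Genes of perivascular, LYVE1-type macrophages were lower, with 20 of 22 tested members negative and a median difference of -1.15 (adjusted p = 1.24e-09, and adjusted p = 0.384 with an estimated correlation). Over all genes 3 members were lower and 0 higher, and adjusted over the list alone 16 were lower and 1 higher. The lower ones were led by Cd209g, Cd209b and Cd209d, the paralogs that their probes may not separate fully. Lyve1 itself differed by -1.02 ± 0.50, with levels that overlapped between the subsets. Timd4, a receptor for phosphatidylserine on dying cells, went the other way at 2.09 ± 0.26 (adjusted p = 0.0706 over all genes). The count of 20 negative members was the same after quantile normalization, median centring and cyclic loess. On the CX3CR1bright arrays of this and the lysosomal and lipid comparisons, keratinocyte and fibroblast markers lay higher, with medians of 1.54 and 0.91.

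Lysosomal genes were lower, with 23 of 25 members negative and a median of -0.34 (adjusted p = 0.00121, and adjusted p = 0.371 with an estimated correlation). After quantile normalization and after cyclic loess 20 members were negative. Over all genes 1 member, Atp6v0d2, was lower, and adjusted over the list alone 2 were, the other being the protease gene Ctsl at -1.19 ± 0.18. The macrosialin gene Cd68 differed by -0.64 ± 0.18 and the progranulin gene Grn by -0.62 ± 0.18, neither past the threshold. Lipid-handling genes had a median of -0.34 over 18 members (adjusted p = 0.0262, and adjusted p = 0.509 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 3 were lower and 1 higher. Abcg1, a cholesterol exporter, differed by -1.07 ± 0.22, the lysosomal lipase gene Lipa by -0.89 ± 0.22 and the phospholipid transfer gene Pltp by -0.78 ± 0.20, while Ch25h, which makes 25-hydroxycholesterol, differed by 0.71 ± 0.18. The lipid call ended with a stricter filter, after quantile normalization, and without CX3CR1low replicate 1 (median -0.38, adjusted p = 0.136) or CX3CR1bright replicate 2 (median -0.28, adjusted p = 0.218), and the median was -0.52 without CX3CR1bright replicate 1. It was -0.21 and -0.20 after quantile normalization and cyclic loess.

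Conventional dendritic cell genes were higher, with 13 of 17 members positive and a median of 0.74 (adjusted p = 3.41e-06, and adjusted p = 0.344 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 7 were higher. Ccr7, the receptor that guides migration to lymph nodes, differed by 2.22 ± 0.22, Flt3, a growth factor receptor of the dendritic lineage, by 2.13 ± 0.24, the chemokine gene Ccl22 by 1.69 ± 0.22 and the integrin gene Itgax by 1.69 ± 0.27. Genes of MHC class II presentation were higher with 13 of 13 members positive, a median of 0.42 (adjusted p = 3.62e-05, and adjusted p = 0.384 with an estimated correlation), 0 past the threshold over all genes and 2 higher adjusted over the list alone. The peptide-loading gene H2-DMb2 differed by 1.66 ± 0.19, and the co-stimulatory genes Cd80 and Cd86 by 0.84 ± 0.20 and 0.46 ± 0.18. Without CX3CR1bright replicate 1 the medians were 0.49 for the dendritic list and 0.20 for MHC class II. Langerhans cell genes had a median of 1.65 over 9 members (adjusted p = 0.00121, and adjusted p = 0.384 with an estimated correlation), 0 past the threshold over all genes and 4 higher and 1 lower adjusted over the list alone. Cd207, the langerin gene of Langerhans cells and some dendritic cells, differed by 2.24 ± 0.28. The decoy receptor gene Il1r2 differed by 1.88 ± 0.23 and the potassium channel gene Kcnn4 by 0.84 ± 0.22. The lower member, Cd209a, differed by -1.30 ± 0.23, and the other tested genes of the Cd209 family had negative differences too. Without CX3CR1bright replicate 2, the array with the most keratinocyte transcripts, the Langerhans median was 0.55. On that array keratinocyte markers lay 2.49 above the CX3CR1low mean, and on CX3CR1bright replicate 1 by 0.52.

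Monocyte genes were higher by the test, with 13 of 17 members positive but a median of 0.12 (adjusted p = 0.00306, and adjusted p = 0.509 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 3 were higher: Ccr2, the receptor that brings monocytes into tissue, at 1.90 ± 0.22, the matrix gene Fn1 at 1.34 ± 0.24 and the proteoglycan gene Vcan at 0.86 ± 0.18. The call ended without CX3CR1low replicate 2 (median 0.097, adjusted p = 0.0958) or CX3CR1bright replicate 1 (median 0.22, adjusted p = 0.0967), and the median was 0.47 without CX3CR1low replicate 1, 0.35 without CX3CR1bright replicate 2, and 0.22 and 0.21 after quantile normalization and cyclic loess. Inflammatory cytokines and NF-kB targets were higher, with a median of 0.52 over 25 members (adjusted p = 0.000143, and adjusted p = 0.409 with an estimated correlation), or 0.33 without CX3CR1low replicate 2. Over all genes 0 passed, and adjusted over the list alone 8 were higher and 4 lower. Il12b, a subunit of interleukin-12 and interleukin-23, differed by 2.07 ± 0.38. The interferon-induced chemokine gene Cxcl10 differed by 1.34 ± 0.28 and the NF-kB inhibitor gene Tnip3 by 1.13 ± 0.18. The 4 lower members were Ccl7, a monocyte attractant, at -0.82 ± 0.19, Ccl12 at -0.89 ± 0.24, Ccl2 at -0.72 ± 0.18 and Tnf at -0.60 ± 0.18. Cell cycle genes were higher, with 18 of 25 members positive and a median of 0.41 (adjusted p = 7.84e-05, and adjusted p = 0.344 with an estimated correlation), or 0.64 without CX3CR1low replicate 2. None passed over all genes, and 0 passed adjusted over the list alone (limma, 9 at an unadjusted p under 0.05). The mitotic genes Bub1b, Cenpf and Kif11 differed by 0.84 ± 0.18, 1.01 ± 0.24 and 0.91 ± 0.23, at low levels in both subsets. On the same CX3CR1bright arrays, markers of keratinocytes and fibroblasts lay higher too, with medians of 1.54 and 0.91. So did conventional dendritic cell and Langerhans cell genes, with medians of 0.74 and 1.65. Which cells carried the monocyte, inflammatory and cell cycle transcripts was not tested.

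**Figure D2:**
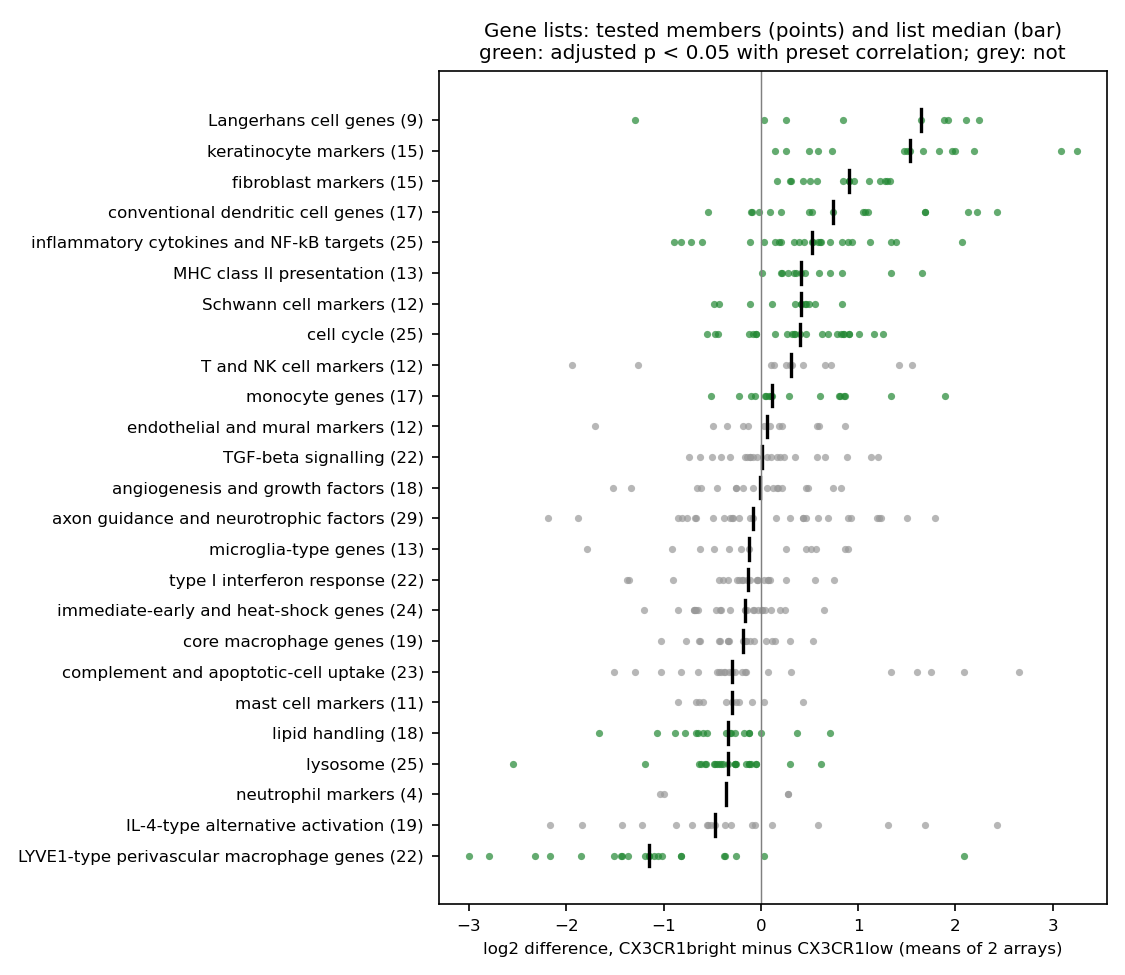
Log2 difference, CX3CR1bright minus CX3CR1low, of each tested member (points) and the median (bar) of the 25 gene lists, with the number tested in brackets and green for lists past the threshold with a preset correlation. Medians run from -1.15 for LYVE1-type genes to 1.65 for Langerhans cell genes.

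In the macrophage lists that did not pass, members went both ways. Of the complement and apoptotic-cell uptake genes, 5 were higher and 5 lower adjusted over the list alone and 0 passed over all genes (median -0.29, or -0.20 and -0.19 after quantile normalization and cyclic loess, mean 0.048, camera direction down, adjusted p = 0.774). Axl, Timd4 and the phosphatidylserine receptor gene Havcr2, at 1.61 ± 0.22, had positive differences, and Gas6, the ligand of Axl, differed by -1.51 ± 0.21. Among genes of IL-4-type activation 2 were higher and 4 lower adjusted over the list alone and 0 over all genes (median -0.47, adjusted p = 0.141), with Ccl22 at 1.69 ± 0.22, the lectin gene Clec10a at -1.83 ± 0.28, the chemokine gene Ccl24 at -1.42 ± 0.23 and the transferrin receptor gene Tfrc at -2.16 ± 0.40. Without CX3CR1bright replicate 1 that list passed (median -0.44, adjusted p = 0.0493), and without CX3CR1bright replicate 2 its median was -0.096 (adjusted p = 0.530). Axon guidance genes had 1 higher and 4 lower adjusted over the list alone and 0 over all genes (median -0.079, mean 0.063, camera direction up, adjusted p = 0.790), and the median ran from -0.29 without CX3CR1bright replicate 2 to 0.078 without CX3CR1low replicate 2. The axon guidance median was -0.011 after cyclic loess, 0.17 over 38 members with no filter on dim clusters and -0.34 over 14 with a stricter filter. Members included the semaphorin genes Sema6a at -2.19 ± 0.33, Sema4b at -1.88 ± 0.25 and Sema7a at 1.51 ± 0.26. Of angiogenesis and growth factor genes 1 was higher and 2 lower adjusted over the list alone and 0 over all genes (median -0.0063, and 0.040 and 0.067 after quantile normalization and cyclic loess, adjusted p = 0.774). With 1 array left out that median was -0.24 without CX3CR1low replicate 1, -0.011 without CX3CR1low replicate 2, and -0.18 and -0.14 without CX3CR1bright replicates 1 and 2. The growth factor genes Hbegf and Pdgfc differed by -1.51 ± 0.21 and -1.34 ± 0.20, and Pdgfb by 0.83 ± 0.18. TGF-beta signalling genes had a median of 0.011 (adjusted p = 0.323), with 1 member higher adjusted over the list alone, the receptor gene Tgfbr1 at 1.20 ± 0.20, and 0 over all genes. That median was 0.091 and 0.11 after quantile normalization and cyclic loess, -0.094 and 0.16 without CX3CR1low replicates 1 and 2, and -0.069 and -0.054 without CX3CR1bright replicates 1 and 2.

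Microglia-type genes had 1 member higher and 2 lower adjusted over the list alone and 0 over all genes (median -0.13, or 0.00028 and 0.012 after quantile normalization and cyclic loess, mean -0.069, camera direction up, adjusted p = 0.841), and the median ran from -0.34 without CX3CR1low replicate 2 to 0.12 without CX3CR1bright replicate 2. The adhesion receptor gene Adgrg1 differed by -1.78 ± 0.23, Bin1 by -0.91 ± 0.21 and Golm1 by 0.89 ± 0.21. Interferon response genes had a median of -0.13 (adjusted p = 0.520), with 2 lower adjusted over the list alone and 0 over all genes, the oligoadenylate synthetase family genes Oasl1 and Oas2 at -1.36 ± 0.22 and -1.37 ± 0.28. The interferon median was -0.21 without CX3CR1bright replicate 1, -0.034 without CX3CR1bright replicate 2 and -0.016 after cyclic loess, where 11 of 22 members were positive. Immediate-early and heat-shock genes, which respond to tissue digestion, had a median of -0.16 (adjusted p = 0.0977), with 1 lower adjusted over the list alone, Jund at -1.20 ± 0.21, and 0 over all genes. Their median was -0.25 without CX3CR1bright replicate 1, and -0.092 and -0.063 after quantile normalization and cyclic loess. Core macrophage genes had a median of -0.18, or -0.081 and -0.049 after quantile normalization and cyclic loess (adjusted p = 0.144), with 0 past the threshold over all genes and 0 adjusted over the list alone (limma, 4 at an unadjusted p under 0.05). The complement receptor gene C5ar1 differed by -1.03 ± 0.24, and relative to the CX3CR1low mean the list median was -0.24 and -0.23 on CX3CR1bright replicates 1 and 2. Without a filter on dim clusters the immediate-early, core macrophage, IL-4-type and mast cell lists passed, and the immediate-early list also with all clusters or an intensity trend.

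Markers of other skin cells were measured in the same sorts. Keratinocyte markers were higher, with 15 of 15 members positive and a median of 1.54 (adjusted p = 3.67e-06, and adjusted p = 0.498 with an estimated correlation), but 0 passed over all genes and 0 adjusted over the list alone (limma, 6 at an unadjusted p under 0.05). The basal keratin gene Krt15 differed by 3.25 ± 0.71 and the desmosomal genes Dsc3 and Dsg1a by 2.20 ± 0.57 and 1.54 ± 0.42. The difference was uneven between arrays: without CX3CR1bright replicate 2 the median was 0.52, and without CX3CR1bright replicate 1 it was 2.49. Fibroblast markers were higher, with 15 of 15 members positive and a median of 0.91 (adjusted p = 1.31e-08, and adjusted p = 0.344 with an estimated correlation), 0 past the threshold over all genes and 8 higher adjusted over the list alone. The collagen genes Col1a1, Col1a2 and Col3a1 differed by 1.33 ± 0.19, 1.11 ± 0.18 and 1.29 ± 0.26, and the median was 0.92 on CX3CR1bright replicate 1 and 0.85 on replicate 2.

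Schwann cell markers had a median of 0.41 over 12 members (adjusted p = 0.0262, and adjusted p = 0.409 with an estimated correlation), with 0 past the threshold over all genes and 0 adjusted over the list alone (limma, 1 higher and 1 lower at an unadjusted p under 0.05). The sodium channel gene Scn7a differed by 0.83 ± 0.19 and the myelin gene Pmp22 by -0.48 ± 0.18. That call ended after quantile normalization or cyclic loess, under an intensity trend, without CX3CR1low replicate 2 (median 0.22, adjusted p = 0.0943) and without CX3CR1bright replicate 2 (median 0.30, adjusted p = 0.0800). T and NK cell markers did not pass (median 0.31, adjusted p = 0.0977), with 1 higher and 1 lower adjusted over the list alone and 0 over all genes, but passed without a filter on dim clusters, without CX3CR1low replicate 1 (median 0.60, adjusted p = 0.0189) and without CX3CR1bright replicate 2 (median 0.74, adjusted p = 0.00104). Their positive median rested on CX3CR1bright replicate 1, without which it was -0.012 (adjusted p = 0.896), and it was 0.17 without CX3CR1low replicate 2. The interleukin-7 receptor gene Il7r differed by 1.56 ± 0.18 and Cd4 by -1.94 ± 0.25, and the T cell receptor gene Cd3g had levels of 6.88 and 5.43 on the CX3CR1bright arrays and 4.83 and 4.64 on the CX3CR1low arrays. Mast cell markers (median -0.30, adjusted p = 0.111) and endothelial and mural markers (median 0.068, mean -0.022, camera direction up, adjusted p = 0.389) had 0 members past the threshold over all genes and 0 adjusted over the list alone (limma, 3 and 2 at an unadjusted p under 0.05). Without CX3CR1bright replicates 1 and 2 the mast cell median was -0.47 and -0.19, and after quantile normalization and cyclic loess it was -0.18 and -0.16. The endothelial median ran from -0.013 without CX3CR1low replicate 2 to 0.16 without CX3CR1bright replicate 2 and was 0.14 after cyclic loess and 0.40 over 4 members with a stricter filter. Of 4 tested neutrophil markers (median -0.36, adjusted p = 0.441) 1 was lower adjusted over the list alone, Mmp9 at -0.99 ± 0.18, and 0 over all genes, and the median was -0.18 without CX3CR1bright replicate 1.

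**Figure D3:**
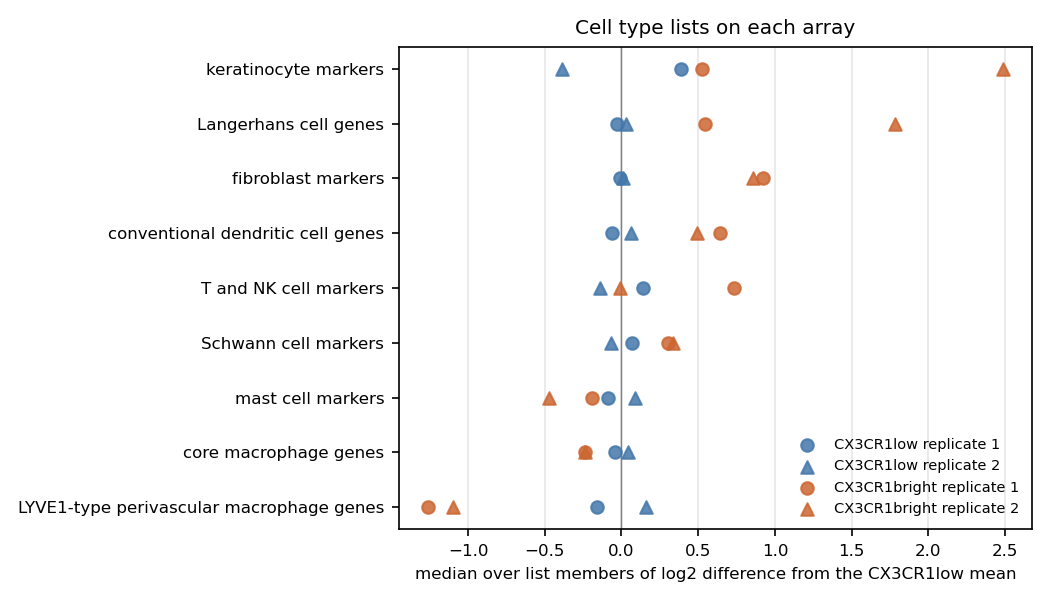
Median over list members of the log2 difference from the CX3CR1low mean, on each of the 4 arrays, for 9 lists of macrophage and other cell type genes. Keratinocyte markers lie at 0.52 and 2.49 on CX3CR1bright replicates 1 and 2, and fibroblast markers at 0.92 and 0.85.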

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

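The combination of intensity trend and robust prior was chosen after the data had been seen; the other alternatives were planned. The count of 18 genes stayed within 1.5 times under 2 of 18 alternatives, the mean of a gene's clusters (19) and median centring (17). It became 1 with no filter on dim clusters, with all clusters, after quantile normalization, with a robust prior, at an adjusted p under 0.01 and in the test against a 1.5-fold difference. It became 33 with cyclic loess, 293 at an adjusted p under 0.10, 308 with an intensity trend, 321 with trend and robust prior and 464 with a stricter filter, which tested 7327 genes, and it ranged from 0 to 154 with an array left out, the higher count without CX3CR1bright replicate 1 and 0 without any other. With the replicate number as a block it was 0 (limma, 2637 genes at an unadjusted p under 0.05), and Cx3cr1 differed by 4.82 with an adjusted p of 0.129; 13 lists passed, the 12 and T and NK cell markers. The deviations of same-numbered arrays from their group means correlated at 0.155 across genes, over 2 pairs, and the labels name no shared litter. With an array left out Cx3cr1 differed by 4.80 to 4.83, with adjusted p-values of 0.0244 to 0.248. The direction of the 18 genes was the same in all 270 values over 15 alternatives, and 129 of these were past the threshold. The shared direction was all but fixed, since these genes had no overlap between the groups and several settings refit the same difference. Over all named genes besides Cx3cr1, called or not, 1608 values kept their direction and side of the threshold, 211 passed under the alternative alone and 137, all of called genes, lost the call. For single lists these numbers were 389, 12 and 34. Lists past the threshold numbered 0 with an estimated correlation (camera, 3 at an unadjusted p under 0.05), 2 with fry and 10 to 17 under the other 16 alternatives, against 12. The test's direction turned for lists that did not pass: microglia-type genes with no filter (median -0.12), a stricter filter (-0.21), an intensity trend with or without the robust prior and fry (-0.13 each) and with an array left out (-0.34 to 0.12); complement genes with a stricter filter (-0.30) and an array left out (-0.30 to -0.24); axon guidance genes with a stricter filter (-0.34), fry (-0.079) and an array left out (-0.29 to 0.078); neutrophil markers with no filter (-0.00084); and endothelial markers with an array left out (-0.013 to 0.16). With an array left out Cxcr2 ranged from -0.081 to 0.63 and Ltf from -0.12 to 0.67. Apart from the fewer genes or arrays that some alternatives use, the cause was not tested. Signal over background limits dim genes, such as Cx3cr1 in CX3CR1low cells at 3.62.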

Other observations

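The 6 tests on the source of keratinocyte, fibroblast and dendritic cell transcripts were chosen after the results were seen, as were the genes in the next paragraph.

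Some genes outside the fixed lists also had large differences, CX3CR1bright minus CX3CR1low, with no overlap between the subsets, though none of those named here passed the threshold (limma, adjusted p = 0.0541 to 0.0850). Among complement genes, C4b stood at -2.58 ± 0.26 (SE, n = 2 per subset), C2 at -1.49 ± 0.21 and the properdin gene Cfp at -1.61 ± 0.23. Of lysosomal enzymes that degrade glycosaminoglycans, Sgsh differed by -1.79 ± 0.26 and Naglu by -1.51 ± 0.20, and the glycogen-degrading Gaa by -1.44 ± 0.21. The water channel gene Aqp1 differed by -1.89 ± 0.21, the growth factor receptor gene Fgfr1 by -1.58 ± 0.18, the dynamin gene Dnm1 by -2.45 ± 0.24 and the epithelial cytokine gene Tslp by -1.84 ± 0.19. In the other direction lay the chemokine receptor gene Ccr1 at 1.58 ± 0.18, the tetraspanin gene Cd9 at 1.55 ± 0.18, the actin regulator gene Coro1a at 1.80 ± 0.18, the collagenase gene Mmp13 at 2.46 ± 0.27 and the ectonucleotidase gene Nt5e at 2.64 ± 0.40. The semaphorin receptor gene Plxna4 differed by 2.21 ± 0.31 and the intermediate filament gene Nes by 1.49 ± 0.20. Nt5e and Nes had CX3CR1low means of 3.64 and 3.39, below the array medians, so these differences are limited by background. The CX3CR1low mean of Plxna4, 3.94, lay near the medians.

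Keratinocyte markers were higher in CX3CR1bright, though sorting for macrophages should remove keratinocytes. On CX3CR1bright replicate 2 the markers lay a median of 1.98 above replicate 1 of the subset, against a gap of 0.772 between the CX3CR1low arrays, and 14 of 15 were higher there. Krt17 and Krt14 were chosen after their values were seen: Krt17 stood at 11.0 on that array and at 4.13 to 5.27 on the others, and Krt14, an abundant keratin, at 10.6 against 7.64 to 8.60. Whether they were also raised in replicate 1 cannot be told apart from array spread, since they lay 0.231 above the higher CX3CR1low array, within that gap, although 11 of 15 lay above both CX3CR1low arrays and the list passed without replicate 2 (median 0.52, adjusted p = 0.000204). The 1.98 restates the uneven arrays, so keratinocyte RNA in replicate 2 and expression by the subset, uneven between pools, both stay open.

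Fibroblast markers were higher on both CX3CR1bright arrays, though sorting for macrophages should remove fibroblasts, and the collagen gene Col14a1, chosen after its values were seen, differed by 4.41 ± 0.45 (limma, adjusted p = 0.0541). Its CX3CR1low levels, 3.25 and 3.56, lay below the array medians and can be background, against 7.17 and 8.47 on the CX3CR1bright arrays. More fibroblast RNA in these sorts and expression of the markers by the subset cannot be told apart: the 5 brightest markers differed by a median of 0.846 against 0.910 for the list, but as all 15 were positive this outcome was all but fixed. Col14a1 exceeded the largest marker difference, 1.33 for Col1a1, by 3.08 with an SE of 0.487, but a difference from background is not comparable with that of a gene above the array medians in both subsets, so fibroblast RNA stays open for it. Expression of Col14a1 by CX3CR1bright macrophages stays open too and was not tested.

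Dendritic and Langerhans cell genes were higher in CX3CR1bright, though the sort was for macrophages. Either cell type could be a source, as could the subset itself, which was not tested. On CX3CR1bright replicate 1, which had fewer keratinocyte transcripts, Epcam, Cdh1 and Cldn1 lay a median of 0.547 above the CX3CR1low mean, against 1.97 for Cd207 and Il1r2. Langerhans cells cannot be told apart from other sources on this value, since keratinocytes also express Epcam, Cdh1 and Cldn1. For XCR1-type dendritic cells the tested members differed by a median of 0.295, or 0.847 with 2 SE added, but 2 of 6 lay above the 75th percentile, too few to exclude them. Of the dendritic list, 4 of 17 tested genes are also in another list, and of the Langerhans list 1 of 9. Other lists share members too, with 7 of 22 for LYVE1-type genes, 2 of 13 for MHC class II and 2 of 17 for monocyte genes. For inflammatory genes the count was 2 of 25.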
